A study of Caenorhabditis elegans with 14 samples.

How the data were processed

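The labels name C. elegans embryos as the source of all 14 libraries, 1 per group, and each comparison set 1 library against 1 other. Per the labels' protocols, RNA of 20 to 30 nt was purified on a gel and treated with phosphatase (CIAP) and polynucleotide kinase before ligation, which lets RNAs with 5′ triphosphates, such as secondary siRNAs, enter the library along with fragments of longer RNAs, and was sequenced on an Illumina HiSeq instrument. NRDE-3 was pulled down through a FLAG tag with the M2 antibody. Per the labels, every eri-1 library carries eri-1(mg366) and a 3xflag::gfp::nrde-3 transgene, the NRDE-3 library of N2 carries the transgene, and the labels of the total libraries of N2, susi-1(R457H) and N2 after cold shock and of the tail libraries of N2 and susi-1(ust1) name none. For the tails, a linker was ligated to RNA 3′ ends, and products of reverse transcription were amplified by PCR with a primer in 26S rRNA, per the labels' protocols. The growth protocols, per the labels, also mention larvae released onto plates, with food for most libraries and without food for the UV experiment, where bleached embryos were irradiated. How the plates without food relate to the embryos sampled is not given in the sources used here.

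The deposited small RNA files hold counts of reads per transcript or RNA in whole numbers, split per the file headers into sense and antisense reads. The authors' aligner is named as Bowtie2 in the submitters' processing notes, with a version and role not given in the sources used here. The genome build, annotation release and treatment of reads with several matches are likewise not given in the sources used here. Identical copies have about even counts, so members of copied families (5S rRNA, tRNAs, histones) are described mainly as groups. Values of single tRNA and histone genes named by the rule below are uncertain, since their reads may come from other copies. The deposited tail files hold counts of reads per added sequence, with a total and a count of ends without one. In the 3 eri-1 tail libraries every deposited count is a multiple of 4, so these counts were divided by 4 before any interval or test. How the added sequences were separated from 26S rRNA and which lengths were kept is not given in the sources used here.

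Counts were summed over the 56374 entries of the small RNA tables to 45510 genes, of which 44852 matched the Ensembl 115 annotation of build WBcel235 by WormBase gene ID and 658 did not. All coordinates come from that match, and no base of the genome was used. Truncated lines without a gene name, from 0 to 3 in a library, were left out, at most 0.00052% of reads. Antisense reads were the measure for rRNA and protein-coding genes and sense reads for microRNAs, piRNAs, tRNAs, snRNAs and snoRNAs, as set before the data were examined. For classes not named in that plan, antisense reads were taken for ncRNAs, lincRNAs, transposons and pseudogenes and sense reads for mitochondrial genes and splice leaders, a choice made after seeing the data. Ratios of rRNA were taken over assigned reads, and those of all other genes over non-rRNA reads.

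Each ratio has an exact conditional binomial (Clopper-Pearson) 95% interval, and shares have exact binomial ones. A gene at 0 was set to 3 counts, a floor of 0.290 to 0.748 per 1000000 assigned reads, to give the bound of a fold from counting error alone. Genes with 50 or more reads in a pair were called at least 2-fold apart where the ratio was 2 or more, or 0.5 or less, and the interval excluded 1. This is a rule of size, and no p across genes was computed. Before the data were examined, 33 gene lists were fixed: 4 of rRNA, and 29 others of RNA classes, microRNA families, targets of ERGO-1 and WAGO, germline, small RNA, ribosome, histone, DNA damage and stress genes, tissue markers and the mitochondrial genome. The histone list took every gene named his-, and so holds his-17, which is not a histone. Members with 20 or more reads in the pair entered, with 0.5 reads added to both counts of a log2 ratio. Where 3 or more members did, their median log2 ratio was given its percentile among 10000 random lists of the same size, drawn within 20 bins of mean count, as a description of these libraries. Copied genes, such as tRNAs and histones, may share reads and are then not independent members. Counts of members and percentiles of such lists may therefore overstate a difference.

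The genes named were chosen by a rule fixed before the data were examined. It takes all rRNA genes, and among genes with 200 or more reads in the pair the 6 highest and 6 lowest by the interval bound nearest 1. It also takes the 3 most abundant microRNAs of a pair, the 3 members of each described list with the most reads, the 5 most abundant tails of a library and each U tail length with 10 or more reads. Tail shares were compared between 2 libraries with Fisher's exact test, two-sided, and mean tail lengths with 2000 bootstrap draws. The 8 main comparisons were 5 of small RNA and 3 of tails, and 3 comparisons of NRDE-3-bound with total RNA were secondary.

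Alternatives set before the data were examined were DESeq2 size factors, edgeR TMM factors and total microRNA reads as scaling of genes, and for rRNA total microRNA reads, non-rRNA reads or the median ratio of genes with 20 or more reads in both libraries (the 20-read median). The others were other read minimums, the other strand, other definitions of a U tail, and each distinct tail counted once. The 3 copies of 5S rRNA with mostly antisense reads were left out, or had their strands exchanged together with own-strand reads of F31C3.13 to F31C3.16 added, as alternatives chosen after seeing the data, as were DESeq2 size factors for rRNA, which rest on all genes with a read in both libraries. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, were used.

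The steps were tested on simulated counts with 200 changed genes per pair, drawn with counting (Poisson) error only. The simulated pairs hold no spread between cultures or PCR copies, so they give no rate of false calls for the real pairs. Genes changed 3-fold were recovered in 48 of 49 cases for susi-1(R457H) against N2 (2178 genes), 42 of 44 for N2 after cold shock (1895 genes), 41 of 45 for UV in total RNA (4978 genes), 41 of 41 for UV with NRDE-3 (946 genes) and 47 of 48 for eri-1 against N2 with NRDE-3 (3449 genes). Genes not changed were called in 10 of 1980, 7 of 1703, 25 of 4781, 2 of 747 and 48 of 3259 cases in the same order. Intervals held the true ratio for 95.5% to 96.8% of genes.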

Results

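Small RNAs and the 3′ ends of 26S ribosomal RNA (rRNA) were sequenced from the nematode Caenorhabditis elegans, with embryos named as the source by the labels, in 14 libraries, 1 for each group, so there were no replicates. Of these, 5 held total small RNA: the wild-type strain N2, susi-1(R457H), N2 after cold shock, and eri-1(mg366) without and with ultraviolet light (UV). A further 4 held small RNA pulled down with NRDE-3, an Argonaute protein that carries small interfering RNAs (siRNAs) into the nucleus: N2 after cold shock and eri-1(mg366) after cold shock, without UV and with UV. The other 5 held 26S rRNA ends from N2, susi-1(ust1), eri-1(mg366), eri-1(mg366);susi-1(ust1) and eri-1(mg366) after cold shock. Cold shock was 12 h at 4 °C with 2 h of recovery at 20 °C, and UV was a dose of 50 mJ/cm2 with 2 h of recovery.

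Reads assigned to genes numbered 6161946 in N2, 6266873 in susi-1(R457H), 8336035 in N2 after cold shock, 10269803 in eri-1 without UV and 9877973 in eri-1 with UV. The NRDE-3 libraries had 4013277 in N2 after cold shock, 5738974 in eri-1 after cold shock, 10349062 in eri-1 without UV and 10198787 in eri-1 with UV. Most were rRNA, mainly of the rRNA's own strand, from 51.8% in the NRDE-3 library of N2 to 95.6% in N2 after cold shock, so the reads left for all other genes ranged from 357435 to 3123387. The tail libraries listed 11202100 reads in N2, 10798391 in susi-1(ust1), 15591048 in eri-1, 15210416 in eri-1;susi-1(ust1) and 8190556 in eri-1 after cold shock. Levels are given as counts per 1000000 reads (CPM): of assigned reads for rRNA, of non-rRNA reads for all other genes, and of listed reads for tails. All intervals are 95% intervals of counting error only. They leave out the spread between embryo cultures and between PCR copies, since no molecular identifiers were used.

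The mutated genes were examined first. The gene disl-2, which is susi-1, a relative of the exonuclease DIS3L2 that degrades uridylated RNA, had 79 antisense and 9 sense reads in N2 and 26 and 18 in susi-1(R457H). The gene eri-1, an exonuclease needed to make the siRNAs of the Argonaute ERGO-1, had 17 antisense and 12 sense reads in N2 and 11 and 1 in eri-1 without UV. Small RNA reads do not measure messenger RNA, and neither mutation can be read from them. The targets of ERGO-1 separated the strains as labelled. Antisense reads on 16 of them numbered 11467 in N2 (10699.8 CPM), 8838 in susi-1(R457H) (13929 CPM) and 2426 in N2 after cold shock (6575 CPM). In eri-1 there were 191 without UV (135 CPM) and 479 with UV (153 CPM). In the NRDE-3 library of N2 after cold shock they took 665918 reads, 34.4% of all non-rRNA reads, against 537 in that of eri-1 after cold shock (1502 CPM). Both NRDE-3 libraries of the UV experiment had 0, which by counting error alone allows up to 1.68 CPM without UV and 2.76 with UV. These 0s cannot speak to the strain, since the 2 libraries detected only 1185 and 1298 genes. The 6 germline targets of the WAGO Argonautes also had 0 reads there without UV, and 234 with UV.

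**Figure D1:**
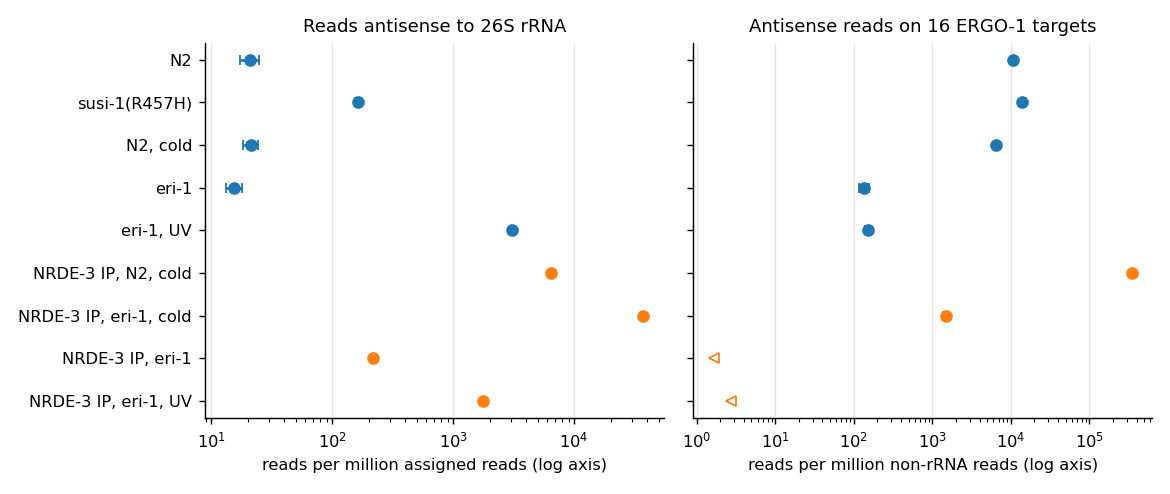
Reads antisense to 26S rRNA in CPM of assigned reads (left panel) and antisense reads on 16 ERGO-1 targets in CPM of non-rRNA reads (right panel), both on log axes, in the 5 total (blue) and 4 NRDE-3 (orange) libraries; points are single libraries, bars are exact 95% counting intervals and open triangles are libraries with 0 reads drawn at the level of 3 counts. The 26S values run from 15.5 in eri-1 without UV to 36815 in the NRDE-3 library of eri-1 after cold shock, and the ERGO-1 target values reach 344454 in the NRDE-3 library of N2.

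The comparison of susi-1(R457H) with N2 asked whether this mutation of susi-1 alters siRNAs against rRNA (risiRNAs), which are antisense to it. Reads antisense to 26S rRNA (rrn-3.1, I:15064838-15068346, build WBcel235) were 7.81-fold higher in the mutant (6.50 to 9.46), at 1025 reads or 164 CPM against 129 reads or 20.9 CPM. Those antisense to 18S rRNA (rrn-1.1, I:15062083-15063836, and rrn-1.2, I:15069280-15071033) were 10.8-fold higher (5.99 to 21.5), at 132 against 12 reads. No difference was detectable at this depth for 5.8S rRNA (rrn-2.1, I:15064301-15064453), with 21 against 24 reads and a ratio of 0.860 (0.456 to 1.61), or for 13 copies of 5S rRNA (rrn-4.16 on chromosome I, the others on V), with 17 against 10 reads and a ratio of 1.67 (0.723 to 4.08). All rRNA genes together gave 2.71 (2.68 to 2.73), a value dominated by 3 other 5S copies, rrn-4.2, rrn-4.3 and rrn-4.4, in which 98.4%, 98.7% and 98.6% of reads over all libraries were counted as antisense against 1.05% in the 13 others. With these copies the 5S genes gave 2.69. Other scalings were total microRNA reads, non-rRNA reads, the median ratio of genes with 20 or more reads in both libraries (the 20-read median) and DESeq2 size factors. By these, in that order, the 26S ratio was 34.9, 13.4, 11.8 and 23.8, and that of 5.8S 3.84, 1.48, 1.30 and 2.62. Sense reads of nrde-3 made up 0.112% of protein-coding sense reads in susi-1(R457H), 0.0120% in N2 and 0.0476% in N2 after cold shock. The eri-1 total libraries, labelled with an nrde-3 transgene, had 0.0902% and 0.168%. If susi-1(R457H) carries a transgene that its labels do not name, its effect cannot be told apart from that of the mutation.

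Among other genes in susi-1(R457H), reads of snoRNAs and tRNAs were higher and antisense reads of protein-coding genes and microRNA reads were lower. The library also held more rRNA (89.9% of reads against 82.6% in N2), and antisense reads made up 30.5% of its protein-coding reads against 57.96%. The snoRNAs, which guide rRNA modification, had 75 of 125 measured members at least 2-fold higher and 0 lower, with a median log2 ratio of 1.12 that lay at the 100th percentile of random lists. Of the tRNAs 124 were higher and 2 lower (0.72, 100th percentile), of the snRNAs 18 and 1 (0.58, 100th percentile), and of other noncoding RNAs 151 and 31 (0.82, 100th percentile). Antisense reads were the measure for ncRNAs, and some ncRNAs, such as T19C4.19, lie opposite tRNAs. The list of other noncoding RNAs may thus recount tRNA reads, here and in the later comparisons, and is not independent of the tRNA list. The snoRNAs T26A8.6 and F30H5.4 were 4.32-fold (3.96 to 4.72) and 5.095-fold (3.79 to 6.94) higher. The tRNA Y40A1A.5 was 5.99-fold higher (4.91 to 7.35), and T19C4.19, an ncRNA opposite a tRNA, was 4.27-fold higher (3.95 to 4.61). MicroRNAs had 2 members higher, 50 lower and 17 neither (−1.38, percentile 0.06), and their share of non-rRNA reads was 7.58% against 19.7%. The mir-35 family of embryonic microRNAs was lower in all 7 measured members (−1.81, percentile 1.39) and by 3.46-fold in sum (3.38 to 3.54), with mir-35 itself 3.44-fold lower (3.34 to 3.54). The family's median was −0.98 with DESeq2 size factors and −0.43 when scaled to total microRNA reads. The most abundant microRNAs mir-57 and mir-82 were at 0.433 and 0.447 times N2, but at 1.12 and 1.16 times N2 when scaled to total microRNA reads. By the same scaling the mir-51 family (median −1.36, 5 lower and 1 neither), the mir-58 family (−1.13, 3 lower and 1 neither) and tissue microRNAs (−1.37, 6 lower) changed sign. The gene let-7, the single let-7 family member with enough reads, passed neither bound.

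Antisense reads of protein-coding genes, which hold most siRNAs, had a median log2 ratio of −1.28 in susi-1(R457H), with 75 genes higher and 1982 lower, and this median changed sign when scaled to total microRNA reads. Antisense reads of 6 germline targets of the WAGO Argonautes were lower in all 6 (−2.85, percentile 0.02) and by 6.24-fold in sum (5.44 to 7.18). Among them were F15D4.5, 22.8-fold lower (15.6 to 34.8), C38D9.2, 9.62-fold lower, and bath-45, 3.46-fold lower (2.94 to 4.09). Of the ERGO-1 targets 1 was higher, 1 lower and 14 neither (0.20, percentile 73.0). Their median was 1.03 with DESeq2 size factors, 1.08 with TMM and 1.58 with total microRNA reads. Their most-read members were E01G4.5 at 1.07 (1.02 to 1.12), F55C9.3 at 2.14 (2.01 to 2.28) and Y37E11B.2 at 1.31 (1.195 to 1.44). Cuticle collagens were lower in 4 of 6 (−2.31, percentile 0.62), with col-71 4.36-fold and col-111 5.99-fold lower and col-60 at 0.643 (0.338 to 1.17). Pseudogenes were lower in 53 of 82 (−1.55, percentile 0). Ribosomal protein genes were lower in 9 of 10 (−1.82, percentile 3.96), and small RNA pathway genes in 15 of 32 (−1.02, percentile 53.4, with the opposite sign when scaled to total microRNA reads). In that pathway the helicase eri-6 was 7.49-fold lower (6.13 to 9.24), the nuclear Argonaute hrde-1 4.58-fold and the Piwi protein prg-1 2.64-fold. The largest single differences were in F22F1.2 (X:8149559-8150721), with 233 against 2 antisense reads, 197-fold higher (53.9 to 1634), and dot-1.2, 15.7-fold higher (11.2 to 22.4). In the other direction was sqst-1 (IV:12034282-12036891), the selective autophagy receptor, 55.8-fold lower (32.5 to 105). The other genes at the lower end were the transposon F44E2.2, 32.7-fold lower (20.0 to 57.5), C44C1.1, 42.5-fold, Y37D8A.6, 34.1-fold, and Y39C12A.9, 37.9-fold.

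Of 2265 genes with 50 or more reads in this pair, 324 were at least 2-fold higher and 1112 lower, so 22.6% of the genes apart were higher. The median log2 ratio of the compared genes was −0.96. DESeq2 size factors, which rest on all genes with a read in both libraries, shifted the log2 ratios by 0.83, TMM by 0.88 and total microRNA reads by 1.38. The 20-read median, not applied to these counts, would shift them downward. It gave a 26S ratio of 11.8, against 13.4 over non-rRNA reads and 23.8 with DESeq2 size factors. These scalings gave 699 higher and 498 lower (58.4% higher), 712 and 477 (59.9%), and 858 and 270 (76.1%).

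The comparison of N2 after cold shock with untreated N2 asked whether cold stress brings out risiRNAs in total small RNA. Reads antisense to 26S rRNA did not differ in CPM, with 177 against 129 reads and a ratio of 1.01 (0.804 to 1.28). The 18S rRNA had 7 against 12 antisense reads (0.431, 0.144 to 1.19), 5.8S 23 against 24 (0.708, 0.382 to 1.31) and the 13 copies of 5S 16 against 10 (1.18, 0.505 to 2.91), none of them distinguishable from 1 in CPM of assigned reads. All rRNA genes together gave 0.666 (0.658 to 0.673) with the 3 oddly stranded 5S copies and 0.942 without them. The 26S ratio depended on the scaling, at 16.22 over total microRNA reads, 3.99 over non-rRNA reads, 2.096 with the 20-read median and 10.98 with DESeq2 size factors. In the same order 18S was at 6.89, 1.69, 0.891 and 4.67 and 5.8S at 11.3, 2.78, 1.46 and 7.67. Of the reads after cold shock 95.6% were rRNA, against 82.6% in N2.

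Reads of the mitochondrial genome were 7.61-fold higher in N2 after cold shock in sum, with 25 of 28 measured genes higher and 0 lower (median log2 3.29, 100th percentile). The mitochondrial rRNA MTCE.7 was 14.04-fold higher (13.5 to 14.6), MTCE.33 5.18-fold and MTCE.26 1.71-fold, and the tRNA MTCE.10 was 156-fold higher (78.3 to 363). Reads of snoRNAs were higher in 99 and lower in 4 of 126 (2.12, 100th percentile), with T26A8.6 3.55-fold, ZK265.10 3.31-fold and C05H8.3 4.97-fold higher. Reads of tRNAs were higher in 265 and lower in 51 (1.82, 100th percentile), of snRNAs in 22 and 4 (0.43, 100th percentile) and of other noncoding RNAs in 187 and 141 (0.33, 100th percentile). Antisense reads made up 12.8% of protein-coding reads after cold shock and 57.96% in N2. They were lower in 2664 protein-coding genes against 67 higher (−2.96), and those of pseudogenes in 68 of 72 (−3.25, percentile 0) and of germline WAGO targets in all 6 (−2.17, percentile 50.0). ERGO-1 targets were lower in 10 and neither in 5 (−1.93, percentile 24.4), a median that changed sign when scaled to total microRNA reads. Of these E01G4.5 was at 1.11, F55C9.3 4.23-fold lower, and Y37E11B.2 3.83-fold lower but at 1.06 when scaled to total microRNA reads. The germline 21U RNAs (piRNAs) were lower in 23 of 24, with a median of −4.15, or −2.53 with counts of 0 set to 3, at percentile 0.

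MicroRNAs after cold shock went in both directions. The muscle microRNA mir-1 (I:6172662-6172757) was 629.5-fold higher (342 to 1315), with 2167 against 10 reads, and the reads antisense to T09B4.14 on the opposite strand at the same place numbered 1077 against 3 (1043-fold, 356 to 5065). Reads antisense to T09B4.14 lie on the strand of mir-1, so they may be mir-1 reads counted again and are no independent signal. The let-7 family members let-7 and mir-84 were 3.48-fold (2.88 to 4.21) and 30.5-fold (7.46 to 268) higher, and mir-237 of the lin-4 family was 53.7-fold higher (13.9 to 460.2). Tissue microRNAs had 3 higher, 3 lower and 1 neither (−0.84, percentile 74.7), a median that changed sign under each of the 3 other scalings. In the opposite direction mir-57 (II:7850499-7850597) was 85.2-fold lower (73.0 to 100.1), mir-64 77.1-fold (51.8 to 121), mir-65 60.5-fold (40.6 to 94.6), mir-235 112.0-fold (38.2 to 544) and mir-82 20.8-fold lower. The mir-51 family was lower in all 6 members (−3.70, percentile 1.61) and 13.8-fold lower in sum (11.7 to 16.3), with mir-51 15.2-fold, mir-52 12.4-fold and mir-54 17.9-fold lower. The mir-58 family had 1 member higher and 3 lower (−3.32, percentile 6.61). Members of the mir-35 family split, with 2 higher, 3 lower and 3 neither. Of these mir-40 was 20.0-fold lower and mir-39 1.57-fold higher (1.501 to 1.63). The microRNA mir-35 was 3.87-fold lower (3.72 to 4.03) but at 1.05 when scaled to total microRNA reads. The family's median log2 ratio was 0.45 (percentile 78.7) while its summed reads were 2.00-fold lower.

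**Figure D2:**
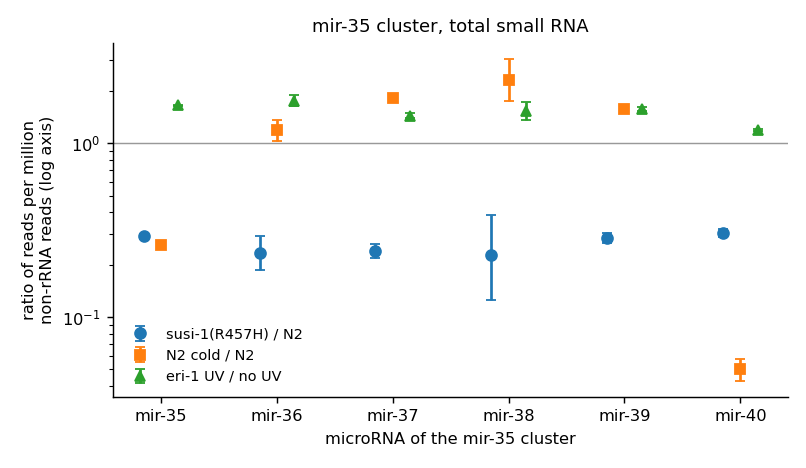
Ratio of CPM of non-rRNA reads (log axis) for mir-35 to mir-40, which are cut from 1 primary transcript, in 3 pairs of total libraries; points are ratios of 2 libraries and bars are exact 95% counting intervals. In the N2 cold shock pair the ratios span 46.5-fold, from 0.0499 for mir-40 to 2.32 for mir-38, while they lie between 0.227 and 0.305 in the susi-1(R457H) pair and between 1.19 and 1.76 in the UV pair.

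All measured members were lower after cold shock for histones, in 3 of 3 (−4.84, or −2.23 with 0 at 3 counts, percentile 0.595), where his-24, a linker histone, was 29.4-fold lower (19.2 to 47.6). Maternal germline genes were lower in 12 of 13 (−3.22, percentile 10.2), small RNA pathway genes in 25 of 29 (−2.85, percentile 16.6) and ribosomal protein genes in 9 of 10 (−3.85, percentile 12.8). The heat shock and cold list was lower in 8 of 9 (−2.73, percentile 36.8), DNA damage genes in 13 of 15 (−3.05, percentile 23.2), rRNA processing factors in 16 of 18 (−3.07, percentile 18.5) and cuticle collagens in 6 of 8 (−2.62, percentile 43.4), none of them apart from other genes with as many reads. The highest protein-coding genes were T05A7.6, with 1044 against 0 antisense reads, at least 1011-fold higher, the C-type lectin clec-38, 1205-fold (333 to 9970.5), and dep-1, a receptor tyrosine phosphatase, at least 311-fold. The lowest were pkd-2, 153-fold lower (118.6 to 202), whose antisense strand holds a snoRNA, and B0041.11, 200.0-fold lower (35.8 to 7914).

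Of 2107 genes compared, 477 were at least 2-fold higher and 1382 lower (25.7% higher), with a median log2 ratio of −2.43. The 20-read median, not applied to these counts, would shift log2 ratios downward, as it gave a 26S ratio of 2.096 against 3.99 over non-rRNA reads. The scalings that were applied shifted log2 ratios by 1.46 (DESeq2 size factors), 1.1003 (TMM) and 2.02 (microRNA total). They gave 667 higher and 947 lower (41.3% higher), 623 and 1126 (35.6%), and 723 and 583 (55.4%). The label of untreated N2 names no matching incubation, so age and cold cannot be told apart in this pair.

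The comparison of eri-1 with and without UV asked whether UV irradiation brings out risiRNAs. The labels of the libraries without UV name no recovery time. UV and the 2 h of recovery therefore cannot be told apart, in total RNA or with NRDE-3. In total small RNA, reads antisense to 26S rRNA were 199.8-fold higher with UV (171 to 235.0), at 30563 reads or 3094 CPM against 159 reads or 15.5 CPM. The 18S rRNA was 129-fold higher (93.9 to 183), at 4716 against 38 reads, 5.8S rRNA 339-fold (184 to 707), at 3260 against 10, and the 13 copies of 5S rRNA 347-fold (176 to 804), at 2668 against 8. All rRNA genes together gave only 1.37 (1.36 to 1.39), since the 3 oddly stranded 5S copies held most of the reads counted as antisense. Without those copies the ratio was 199.3. Scaled to total microRNA reads, non-rRNA reads, the 20-read median and DESeq2 size factors, the 26S ratio was 55.98, 87.1, 90.2 and 77.2.

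Copied histone genes may share reads and are not independent members. Antisense reads of histone genes were higher in 25 of 34 measured genes with UV and lower in 0 (median log2 2.37, 100th percentile). Examples were the replacement histone his-72, 4.85-fold higher (3.24 to 7.55), and his-62, 8.16-fold higher (4.58 to 16.04), with his-24 at 0.902 (0.851 to 0.957). Reads of tRNAs were lower in 272, higher in 5 and neither in 180 (−1.14, percentile 0), or 2.55-fold lower in sum. The tRNA genes C06G1.t4, F41A4.t1, Y54G2A.t1, R03E1.t2 and F28F8.t3 were 6.92-fold (5.42 to 8.92), 6.70-fold, 6.78-fold, 6.03-fold and 5.91-fold lower, and F56F4.11, opposite a tRNA, 6.13-fold lower (5.25 to 7.17). Reads were also lower for snRNAs, in 39 of 76 (−1.07, percentile 0), snoRNAs, in 40 of 126 (−0.74, percentile 0), other noncoding RNAs, in 215 of 472 (−0.87, percentile 0), and piRNAs, in 46 of 260 with 19 higher (−0.35, percentile 0). MicroRNAs made up 39.5% of non-rRNA reads with UV and 25.4% without, with 24 members higher, 3 lower and 71 neither (0.67, 100th percentile). Among these the mir-51 family was 2.06-fold higher in sum (2.02 to 2.09; median 1.00, percentile 99.98), with mir-51 1.98-fold, mir-52 1.90-fold and mir-55 2.08-fold higher. The mir-35 family (0.63, percentile 99.99; mir-35 1.65-fold, mir-39 1.57-fold and mir-40 1.19-fold higher), the mir-58 family (0.62, percentile 99.5) and tissue microRNAs (0.33, percentile 87.4) changed sign when scaled to total microRNA reads. The most abundant microRNAs were mir-82, 1.42-fold higher but lower when scaled to total microRNA reads, mir-57, 1.90-fold higher (1.88 to 1.92), and mir-81, 1.62-fold higher.

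Antisense reads made up 51.1% of protein-coding reads with UV and 38.2% without, and rRNA 68.4% and 86.2% of all reads. Antisense reads of protein-coding genes with UV were higher in 1305, lower in 53 and neither in 4820 (0.40, with the opposite sign when scaled to total microRNA reads). The heat shock and cold list was higher in 6 of 12 (0.91, percentile 99.8), although hsp-1 was at 0.840 (0.696 to 1.02), hsp-90 at 1.18 (0.941 to 1.496) and hsf-1 at 1.09 (0.858 to 1.39). DNA damage genes were higher in 4 of 21 (0.52, percentile 85.8), with the checkpoint kinases atm-1 at 1.505 (1.196 to 1.91), atl-1 at 1.71 (1.24 to 2.40) and chk-2 at 0.914, and small RNA pathway genes were higher in 3 of 37 (0.32, percentile 94.5). Maternal germline genes were higher in 6 of 20 (0.53, percentile 96.0), ribosomal protein genes in 3 of 42 (0.45, percentile 16.3), rRNA processing factors in 3 of 23 (0.42, percentile 73.9), muscle markers in 1 of 3 (0.38, percentile 29.1) and neuron markers in 0 of 5 (0.37, percentile 61.9). The medians of these lists, other than the heat shock and cold list, changed sign when scaled to total microRNA reads. WAGO targets lay near 1, with 6 of 6 neither (−0.01, percentile 61.1), where bath-45 was at 0.906, F15D4.5 at 1.14 and C38D9.2 at 1.01. The single genes farthest apart were hlh-2 (I:7190788-7193920), a basic helix-loop-helix factor, with 661 against 3 reads, 99.9-fold higher (34.0 to 486), and Y59C2A.2, 39.7-fold (23.1 to 74.8). Others were ldb-1, 74.8-fold (20.5 to 620.2), the cohesin subunit coh-1, 49.0-fold (13.4 to 407), the cadherin cdh-4, 32.6-fold (12.6 to 121), and the ncRNA C14F11.14, 69.7-fold higher (23.7 to 339).

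In total RNA with UV, 796 of 5110 genes were at least 2-fold higher and 520 lower (60.5% higher), with a median log2 ratio of 0.17. DESeq2 size factors and TMM shifted log2 ratios by −0.17 and −0.16 and gave 626 higher and 626 lower (50.0% higher) and 635 and 613 (50.9%), whereas the microRNA total shifted them by −0.64 and gave 297 and 1119 (20.97%). The 20-read median, not applied to these counts, would shift them slightly upward, as it gave a 26S ratio of 90.2 against 87.1 over non-rRNA reads.

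**Figure D3:**
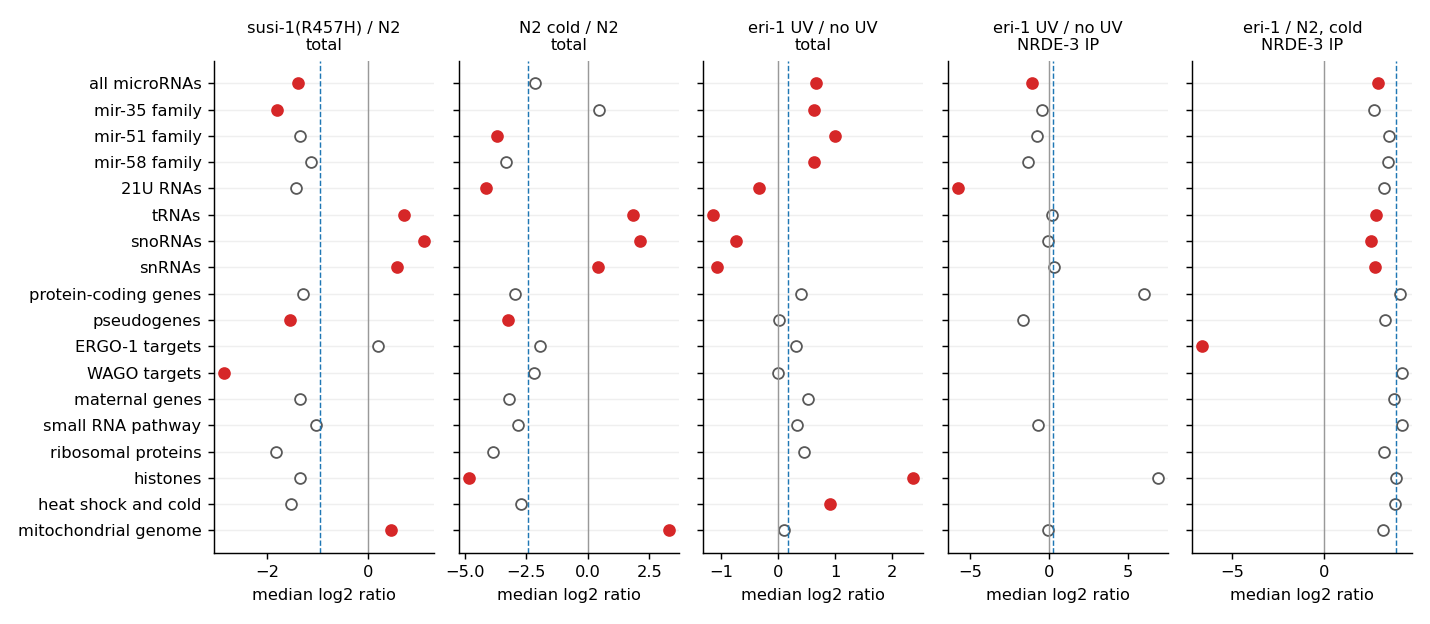
Median log2 ratio (horizontal axes, with a different range in each of the 5 panels) of 18 gene lists in the 5 small RNA comparisons; filled red points lie outside the central 95% of random lists with as many members and similar counts, open grey points within it, and lists with fewer than 3 measured members are left out. The dashed blue line is the median of all compared genes, from −2.43 in the cold shock pair to 3.86 in the NRDE-3 pair after cold shock, and ERGO-1 targets in the latter lie at −6.62.

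In small RNA bound to NRDE-3, reads antisense to 26S rRNA were 8.02-fold higher in eri-1 with UV than without (7.68 to 8.38), at 17928 reads or 1758 CPM against 2268 reads or 219 CPM. The 18S rRNA was 3.57-fold higher (3.17 to 4.04), at 1208 against 343 reads, and the 13 copies of 5S rRNA 5.88-fold (4.501 to 7.79), at 371 against 64 reads. The 5.8S rRNA had 1110 antisense reads with UV and 0 without. All rRNA genes together gave 3.04 (2.98 to 3.09), or 7.82 without the 3 oddly stranded 5S copies. By total microRNA reads, non-rRNA reads, the 20-read median and DESeq2 size factors the 26S ratio was 30.8, 12.97, 11.7 and 11.14. If few distinct molecules were each read many times in these libraries, as considered below for other genes, the counting intervals of these rRNA ratios are too narrow.

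Other genes in these libraries were mostly read in only 1 of them. Of 947 genes with 50 or more reads in the pair, 539 had 0 in 1 of the 2 libraries (56.9%, 53.7 to 60.1), and the NRDE-3 libraries detected 1185 and 1298 genes, against 11878 in that of eri-1 after cold shock. Antisense reads made up 2.15% of protein-coding reads without UV and 4.51% with UV, against 96.3% and 76.1% in the NRDE-3 libraries of N2 and eri-1 after cold shock. The folds given below for genes at 0 are bounds for counting error only. If few distinct molecules were each read many times, these folds bound no difference with UV. Genes with 0 reads without UV were F30H5.4, a snoRNA, with 434 reads with UV (at least 237-fold higher), the anillin gene ani-1, with 351 (at least 192-fold), and pan-1, with 308 (at least 168-fold). Likewise at 0 without UV were toe-1, with 302 (at least 165-fold), the nuclear RNAi gene nrde-2, with 295 (at least 161-fold), and hmg-11, with 294 (at least 161-fold). Genes with 0 reads with UV were mir-1022, with 462 reads without UV (at least 93.8-fold lower), kcmf-1, with 420 (at least 85.3-fold), and mir-74, with 374 (at least 76.0-fold). Likewise at 0 with UV were MTCE.21, with 358 (at least 72.7-fold), mir-245, with 356 (at least 72.3-fold), and famh-161, with 355 (at least 72.1-fold).

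MicroRNAs took 4.42% of non-rRNA reads with NRDE-3 after UV and 10.5% without, and had 13 higher, 35 lower and 20 neither (−1.05, percentile 0), although this median changed sign when scaled to total microRNA reads. The microRNA mir-58 was 2.88-fold lower (2.83 to 2.92), mir-70 5.01-fold lower (4.77 to 5.26), mir-82 2.75-fold lower, and mir-81 2.27-fold lower but at 1.05 when scaled to total microRNA reads. Tissue microRNAs were lower in 5, higher in 1 and neither in 2 (−1.88, percentile 1.39), with mir-228 at 1.12 (1.06 to 1.18) and mir-61 at 0.598 (0.500 to 0.711), and the mir-58 family was lower in 3 of 4 (−1.32, percentile 4.69). The mir-35 family (−0.42, percentile 22.4) and the mir-51 family (−0.74, percentile 17.2) changed sign when scaled to total microRNA reads. Antisense reads of protein-coding genes were higher in 340, lower in 251 and neither in 29, and their median of 6.03, or 3.65 with 0 at 3 counts, was carried by the 523 genes at 0 in 1 library. Reads of piRNAs were higher in 11 and lower in 18 (−5.76, or −3.16 with 0 at 3 counts, percentile 0.745). Some lists had too few measured members for a median. Of these WAGO targets and heat shock and cold genes had 2 higher each, and let-7 and the neuron marker unc-119 were also higher. The maternal germline gene puf-5, the rRNA processing factor nol-6 and the muscle marker myo-1 were lower, each with 0 reads with UV.

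Over all 947 genes compared with NRDE-3, 385 were higher and 326 lower (54.1% higher), with a median log2 ratio of 0.27. Log2 ratios shifted by −0.22 with DESeq2 size factors, −0.27 with TMM and 1.25 with the microRNA total, and the last of these gave 545 higher and 280 lower (66.1% higher).

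The comparison of eri-1 with N2 after cold shock, both with NRDE-3, asked what NRDE-3 carries when the ERGO-1 pathway is absent. Antisense reads on ERGO-1 targets were lower in all 16 measured (median log2 −6.62, or −6.003 with 0 at 3 counts, percentile 0) and 229-fold lower in sum (211 to 250.0). The uncharacterised gene E01G4.5 (II:13472401-13473995), which alone took 30.7% of non-rRNA reads in N2, was 272-fold lower (247 to 301), with 403 against 593290 reads. Among the other targets, F39F10.4 was 97.3-fold lower (71.9 to 135) and Y37E11B.2 130.3-fold lower (86.0 to 208). Other genes that lost as much were W04B5.2, 351-fold lower (219 to 603), Y116F11A.1, 269-fold (219 to 334), F49B2.3, 257-fold (201 to 334), the noncoding linc-22, 226-fold (180 to 288), and the transposon T16A1.9, 349-fold (169 to 868). The microRNA locus mir-260 was also 213-fold lower (118.8 to 426).

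Reads antisense to rRNA with NRDE-3 were higher in eri-1 than in N2 after cold shock. The difference was 5.73-fold for 26S (5.65 to 5.801), at 211280 reads or 36815 CPM against 25802 or 6429 CPM, and 10.35-fold for 5.8S (9.96 to 10.8), at 40681 against 2748 reads. It was 2.80-fold for 18S (2.68 to 2.93), at 9692 against 2418, and 2.37-fold for the 13 copies of 5S (2.29 to 2.46), at 12464 against 3676. All rRNA genes together gave 3.88 (3.85 to 3.92). Scaled in the same 4 other ways, the 26S difference was 14.1-fold, 44.3-fold, 4.09-fold and 3.45-fold.

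In the main scaling most other gene groups were higher in eri-1. The amounts, and for many groups listed below the direction, depended on the scaling. The rRNA took 93.8% of reads in eri-1 and 51.8% in N2, and antisense reads made up 76.1% and 96.3% of protein-coding reads. WAGO targets were higher in all 6 (4.22, percentile 70.3), with F15D4.5 and bath-45 both 19.2-fold and R06C1.4 16.7-fold higher. Small RNA pathway genes were higher in all 24 (4.197, percentile 74.0), with hrde-1 20.2-fold (15.4 to 26.98) and nrde-3 14.5-fold (13.3 to 15.8) higher and eri-6 6.01-fold higher but at 0.468 with DESeq2 size factors. Tissue microRNAs stood above similar genes (4 of 4 higher, 5.20, percentile 98.6). The same held in direction for protein-coding genes (2641 higher, 147 lower, 4.109), histones (33 of 33, 3.90, percentile 16.6), maternal germline genes (16 of 16, 3.75, percentile 25.9), DNA damage genes (8 of 8, 4.12, percentile 51.6), rRNA processing factors (12 of 12, 3.85, percentile 32.1), the heat shock and cold list (9 of 9, 3.84, percentile 27.5) and collagens (4 of 4, 3.96, percentile 37.2). Groups whose medians were higher in the main scaling but lower with DESeq2 size factors and TMM were microRNAs (2.91, percentile 0.1), tRNAs (2.79, percentile 0), snRNAs (2.73, percentile 0), snoRNAs (2.53, percentile 0), other noncoding RNAs (2.80, percentile 0) and pseudogenes (3.30, percentile 6.78). The same was true of piRNAs (3.25, percentile 19.5), the mir-35 family (2.68, percentile 24.0), the mir-51 family (3.48, percentile 28.9), the mir-58 family (3.42, percentile 11.5), ribosomal protein genes (3.23, percentile 20.7), neuron markers (2.27, percentile 1.58) and mitochondrial genes (3.19, percentile 14.4). The microRNA mir-35 was 6.02-fold and mir-37 3.08-fold higher, and at 0.468 and 0.240 with DESeq2 size factors. The genes farthest above N2 were F28C6.5, with 460 against 0 reads (at least 829-fold), and C54E10.1, with 254 against 0 (at least 458-fold). They were followed by the ncRNA F20G2.9, 752-fold (206 to 6239), the cuticlin-like cutl-26, 736-fold (202 to 6105), the autophagy adaptor epg-2, 189-fold (126 to 297), and ZC178.1, with 200 against 4 reads.

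Of 1586 genes compared with NRDE-3 after cold shock, 1413 were higher in eri-1 and 153 lower (90.2% higher), with a median log2 ratio of 3.86. DESeq2 size factors and TMM shifted log2 ratios by −3.68 and −3.66 and gave 360 higher and 356 lower (50.3% higher) and 364 and 353 (50.8%), and the microRNA total shifted them by −1.65 and gave 1238 and 166 (88.2%).

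Set against total RNA of the same treatment, the NRDE-3 libraries held more 26S antisense reads in eri-1 without UV (14.2-fold, 12.0 to 16.7) and after cold shock (303-fold, 261 to 353), and fewer in eri-1 with UV (0.568, 0.558 to 0.579), where the other scalings gave ratios above 1. Scaled to total microRNA reads, non-rRNA reads, the 20-read median and DESeq2 size factors, the difference was 27.4-fold, 11.3-fold, 42.95-fold and 57.1-fold without UV and 99.6-fold, 27.8-fold, 412-fold and 72.9-fold after cold shock. After cold shock 15 of 16 ERGO-1 targets were at least 2-fold higher with NRDE-3 than in total RNA (median log2 4.03). Among genes outside that list Y116F11A.1 was 177-fold and F49B2.3 161-fold higher. The cold shock pair also differs in strain, since its NRDE-3 library carries a tagged nrde-3 transgene and the label of its total library names none. The pairs without and with UV each hold an NRDE-3 library that detected few genes, so their counting intervals may be too narrow.

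The tail libraries asked whether 26S rRNA ends carry more added U in susi-1(ust1) mutants or after cold shock. In all 5 libraries nearly every read was listed with a single nucleotide after the 26S sequence. A lone U made up 74.9% in N2, 76.1% in susi-1(ust1), 80.1% in eri-1, 78.2% in eri-1;susi-1(ust1) and 81.3% in eri-1 after cold shock, and a lone C 22.1%, 20.2%, 15.6%, 19.6% and 17.7%. A lone G made up 2.45%, 2.86%, 2.23%, 1.76% and 0.362% of reads in the same order, and a lone A 0.189%, 0.250%, 0.397%, 0.180% and 0.133%. Counts in the 3 eri-1 libraries were all multiples of 4, and intervals were computed on counts divided by 4. The tail UU followed at 0.0326%, 0.0429%, 0.0456%, 0.0361% and 0.0540%, and no tail was seen in 0.317%, 0.434%, 1.53%, 0.162% and 0.317%.

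Tails of 3 or more U were more frequent in both susi-1(ust1) libraries and after cold shock. In susi-1(ust1) they were at 55.3 CPM against 26.8 in N2, 2.06-fold higher (1.79 to 2.38; Fisher's exact test, two-sided, p = 6.42e-26). In eri-1;susi-1(ust1) they were at 62.6 against 31.3 CPM in eri-1, 2.00-fold higher (1.60 to 2.51; exact p = 1.77e-10), and in eri-1 after cold shock at 178 CPM, 5.70-fold higher (4.63 to 7.05; exact p = 2.80e-74). These tests compare the reads of 2 libraries, not the conditions. Tails of 3 or more nt of any sequence, which include those of U only, were also more frequent. In the same order they were 1.95-fold (1.85 to 2.05), 1.13-fold (1.04 to 1.23) and 3.136-fold (2.91 to 3.38) higher. Those of U followed by A were 2.50-fold, 1.51-fold and 6.23-fold higher. The rise in susi-1(ust1) over N2 was thus not particular to tails of U only. By length, tails of 3 U were 2.05-fold (1.77 to 2.38), 1.85-fold (1.43 to 2.40) and 4.44-fold (3.48 to 5.70) higher in the 3 comparisons, tails of 4 U 2.24-fold (1.27 to 4.08), 2.32-fold (1.39 to 3.97) and 6.04-fold (3.74 to 10.1), and tails of 5 U 20.9-fold (5.15 to 184) after cold shock. Tails of 7 and 8 U were found only after cold shock, at 8.30 and 10.7 CPM, but the longest tail listed was 6 nt in N2 and susi-1(ust1) and 9 nt in the 3 eri-1 libraries. As for N2, the label of untreated eri-1 names no matching incubation, so age and cold cannot be told apart in the tails either.

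Shorter U tails differed less, and not in 1 direction. Nearly all tails of U only were the lone U, which may be a base of the rRNA itself, as taken up below. Ratios over all U tails may thus not measure added U. Tails of U only, of any length, were at 1.016 times N2 in susi-1(ust1) (1.015 to 1.017), at 0.976 times eri-1 in eri-1;susi-1(ust1) (0.974 to 0.978) and at 1.01 times eri-1 after cold shock (exact p = 2.99e-269), with exact p for the first pair of comparisons below the smallest number the test can return. With 2 or more U the ratios were 1.37 (1.32 to 1.43; exact p = 1.15e-51), 0.868 (0.812 to 0.928; exact p = 3.03e-05) and 1.47 (1.38 to 1.58; exact p = 3.07e-28), as the tail UU itself stood at 1.32, 0.791 and 1.18. Mean tail length was 1.00222 nt in susi-1(ust1) and 1.00139 nt in N2, a difference of 0.000830 nt (0.000783 to 0.000880), and 1.00408 nt after cold shock against 1.00184 nt in eri-1, a difference of 0.00224 nt (0.00207 to 0.00242). The difference between eri-1;susi-1(ust1) and eri-1 was 2.70e-05 nt, with an interval from −6.88e-05 to 0.000123.

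**Figure D4:**
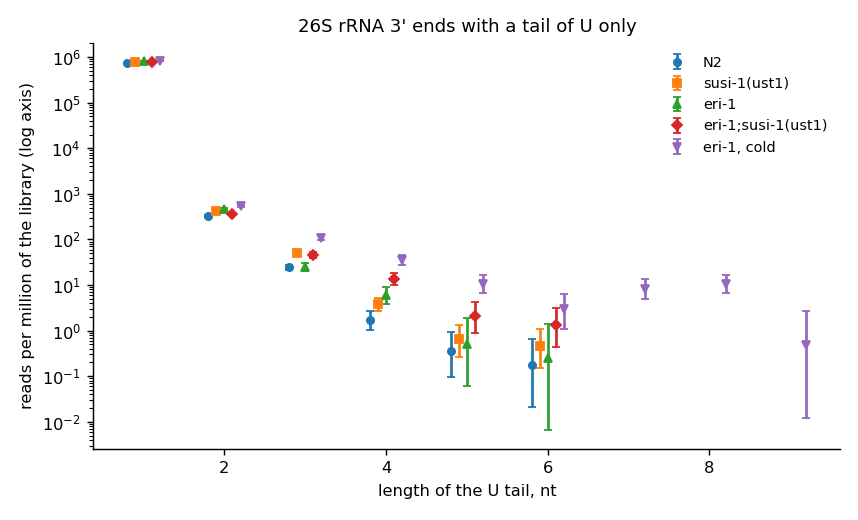
Reads in CPM (log axis) that end in a tail of U only, by tail length from 1 to 9 nt, in the 5 tail libraries; points are single libraries, bars are exact 95% counting intervals, and only lengths with reads are drawn. At 3 U the values are 24.5 in N2, 50.4 in susi-1(ust1), 24.6 in eri-1, 45.5 in eri-1;susi-1(ust1) and 109 in eri-1 after cold shock.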

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

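All tests of explanations in this part were chosen after the results were seen.

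The NRDE-3 libraries of eri-1 without and with UV read few genes many times: 1185 and 1298 genes had a read, against 11878 in the NRDE-3 library of eri-1 after cold shock, and 2.15% and 4.51% of protein-coding reads were antisense, against 76.1% in that library. Lower sequencing depth is not settled by total reads. The shallower of these libraries had 3.04 times the non-rRNA reads of the library after cold shock. Most non-rRNA reads of both, however, were protein-coding sense reads (1482301 without UV and 940374 with UV), which are not the measure for these genes. Antisense protein-coding reads numbered 32551 and 44400, against 221696 in the library after cold shock. Lower depth on the counted strand thus remains open. The 56.9% of well-read genes with 0 reads in 1 of the 2 libraries, against 0.132% to 6.03% in the other main small RNA pairs, is what few distinct molecules amplified many times may give. In the secondary pair after cold shock, 62 of 1121 genes were read only with NRDE-3 and 34 only in total RNA. The other secondary pairs each hold 1 of the NRDE-3 libraries in question. An effect of UV is argued against as the reason for few genes, since the library without UV had fewer still. For which genes were read UV remains open: in total RNA genes read only with UV lay above genes read only without UV by 0.28 in median log2 ratio (0.05 to 0.43), the direction a UV effect would give but under 2-fold.

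In N2 after cold shock microRNAs moved apart from each other. Dilution of all microRNAs alike is argued against, since the log2 ratios of 34 microRNAs with 200 or more reads had an interquartile range of 4.14 (1.80 to 5.83), against 0.58 (0.37 to 0.91) in susi-1(R457H) and 0.61 (0.42 to 1.23) with UV. Among mir-35 to mir-41, which come from 1 primary transcript, members with 200 or more reads in the pair spanned 46.5-fold, from mir-40 at 0.0499 to mir-38 at 2.32, against 1.30-fold in susi-1(R457H) and 2.23-fold with UV, so another cloning bias in this library may account for part of the profile. Older embryos are the biological alternative, and 6 of the 10 measured let-7, lin-4 and tissue microRNAs were higher and 3 lower. Age and cold cannot be told apart here, because the label of the control names no matching incubation.

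The most frequent 26S end in all 5 tail libraries carried a single U. A base of the rRNA itself beyond the matched sequence may account for the U: among tails of 2 or more nt with no U after the first base, at least 94.3% in each library (93.1 to 95.4 in the lowest) began with U, against 75.2% to 81.7% of tails of 1 nt. The genome base at that place was not checked, so how much of the single U was added after transcription remains open. If the first U belongs to the rRNA, each U tail length above holds 1 base that was not added. A tail of 1 U followed by A would then hold only added A. No biological explanation was tested.

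Reads of microRNAs as a share of assigned reads were 3.57-fold higher with UV in total RNA (3.556 to 3.58) and at 0.260 with NRDE-3 (0.258 to 0.263), opposite directions whose difference was not tested. Tails of U only were at 1.016 in susi-1(ust1) over N2 (1.015 to 1.017) and at 0.976 in eri-1;susi-1(ust1) over eri-1 (0.974 to 0.978), again without a test of the difference. Tails of 2 or more U likewise stood at 1.37 (1.32 to 1.43) and 0.868 (0.812 to 0.928), also untested.

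The ncRNAs F31C3.13, F31C3.14, F31C3.15 and F31C3.16 lie opposite or next to the rRNA genes on chromosome I and are listed apart from them. On the opposite strand, F31C3.13 and F31C3.15 lie within rrn-1.2 and rrn-1.1. F31C3.14 (I:15067668-15068355) lies almost wholly within rrn-3.1. F31C3.16 (I:15060861-15061159) overlaps none of the rRNA genes, and had 3771 of the 10322 own-strand reads with UV in total RNA. Own-strand reads of the overlapping ncRNAs are thus largely antisense to rRNA and no independent signal beside the rRNA ratios above. Whether the same reads were counted for both is not given in the sources used here. Own-strand reads of all the F31C3 ncRNAs together stood above the control in each pair. They were 8.73-fold higher in susi-1(R457H) (6.11 to 12.8; 302 against 34 reads), 1.59-fold after cold shock (1.04 to 2.46; 73 against 34), and 383-fold with UV in total RNA (265 to 577; 10322 against 28). With NRDE-3 they were 12.4-fold higher with UV (11.61 to 13.4) and 12.9-fold higher in eri-1 than in N2 after cold shock (12.6 to 13.2). Tails of U followed by A, which are not U only, were 1.73-fold higher in susi-1(ust1) (1.65 to 1.83), 1.55-fold in eri-1;susi-1(ust1) (1.39 to 1.74) and 5.56-fold in eri-1 after cold shock (5.04 to 6.14).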

How the results depend on the processing

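With 1 library per group, no alternative tests the spread between cultures, and depth limits the 18S, 5.8S and 5S ratios of susi-1(R457H) and N2 after cold shock, which rest on 7 to 132 reads. Leaving out 3 copies of 5S rRNA, and exchanging their strands while adding own-strand reads of F31C3.13 to F31C3.16, were chosen after seeing the data, as were DESeq2 size factors for rRNA, and all other alternatives before. The 26S ratios above 2 kept their direction under all 4 other scalings, and the other strand, which is mostly rRNA fragments, is a different measure. Apart from the values below, 416 values of single genes, lists and rRNA parts under an alternative moved beyond their interval (for list medians, by over 0.5). Of these 23 lay on the other side of no change, all from values that passed no call, and 10 were ratios of single rRNAs. A further 232 stayed within it, 15 of them on the other side. So did 30 values that answer a comparison. Where no reason is given, the cause was not tested.

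For all rRNA genes together the ratios below are in the order microRNA total, non-rRNA reads, 20-read median, DESeq2 size factors, other strand, without the 3 copies, and with strands exchanged and the F31C3 reads added. They were 12.1, 4.65, 4.104, 8.26, 1.08, 6.71 and 6.69 in susi-1(R457H), and 10.6, 2.62, 1.38, 7.203, 1.19, 0.942 and 1.00 after cold shock. There the first 5 changed direction, and the intervals of 0.942 (0.769 to 1.15) and 1.00 (0.841 to 1.199) hold 1. With UV in total RNA they were 0.385, 0.599, 0.620, 0.531, 0.785, 199.3 and 220.1, below 1 in the first 5. With NRDE-3 they were 11.7, 4.91, 4.43, 4.22, 1.09, 7.82 and 8.80 for UV, and 9.55, 30.0, 2.77, 2.34, 1.28, 5.53 and 6.47 for eri-1 against N2. For NRDE-3 against total RNA they were 0.405, 0.167, 0.635, 0.844, 1.05, 12.3 and 14.5 without UV, where the last 3 changed direction, 12.3, 1.37, 1.44, 1.93, 1.45, 0.485 and 0.579 with UV, where the first 5 did, and 0.611, 0.171, 2.53, 0.447, 0.512, 323 and 291 after cold shock, where 0.611, 0.171, 0.447 and 0.512 did.

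For 26S antisense reads, with the first 5 of these alternatives, the ratios were 34.9, 13.4, 11.8, 23.8 and 0.972 in susi-1(R457H), 16.22, 3.99, 2.096, 10.98 and 1.30 after cold shock, 55.98, 87.1, 90.2, 77.2 and 0.813 with UV in total RNA, 30.8, 12.97, 11.7, 11.14 and 1.06 with UV and NRDE-3, and 14.1, 44.3, 4.09, 3.45 and 1.29 in eri-1 against N2 with NRDE-3. Direction changed with the other strand in susi-1(R457H) and UV total RNA. For NRDE-3 against total RNA with UV all 5 changed direction, to 15.1, 1.69, 1.77, 2.37 and 1.69, and after cold shock the other strand gave 0.615. Of the smaller rRNAs in the main comparisons, the other strand reversed 18S (0.707), 5.8S (0.673) and the 13 copies of 5S (0.874) with UV in total RNA, and 5.8S (0.838) and the 13 copies (0.709) in eri-1 against N2. The 16 copies of 5S changed direction after cold shock (10.6, 2.61, 1.37 and 7.196) and in eri-1 against N2 (2.41 and 7.57 with microRNA total and non-rRNA reads).

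Counts of genes at least 2-fold apart moved with the number of genes tested: without a minimum they were 3346 in susi-1(R457H), 4759 after cold shock, 2562 and 1161 for UV in total RNA and with NRDE-3, and 8730. for eri-1 against N2, and with 200 or more reads 474, 587, 384, 125 and 402.0. With DESeq2 size factors and TMM the last comparison had 716 and 717, in place of 1566. For eri-1 against N2 with NRDE-3, DESeq2 size factors also turned the median log2 ratios of the mir-35 (−0.999), mir-51 (−0.20) and mir-58 (−0.27) families, all microRNAs (−0.78), piRNAs (−0.44), tRNAs (−0.89), snRNAs (−0.95), snoRNAs (−1.15), pseudogenes (−0.38), other noncoding RNAs (−0.88), ribosomal protein genes (−0.45), neuron markers (−1.41) and mitochondrial genes (−0.50). Single genes that changed direction were mir-57 (1.12) and mir-82 (1.16) in susi-1(R457H), mir-35 (1.05) and Y37E11B.2 (1.06) after cold shock and mir-81 (1.05) for UV with NRDE-3, all with the microRNA total. In eri-1 against N2 they were mir-35 (0.468 and 0.475 with DESeq2 size factors and TMM), eri-6 (0.468 and 0.474) and mir-37 (0.240 and 0.243, and 0.980 with the microRNA total).

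For tails of U only, counting each distinct sequence once gave ratios of 0.860 in susi-1(ust1), 1.04 in eri-1;susi-1(ust1) and 0.887 after cold shock, each in the other direction, since sequences with few reads then weigh as much as the lone U. With 3 or more U the ratio of eri-1;susi-1(ust1) was 2.00, the reverse of that for any U tail, with 2.06 and 5.70 in the other pairs, and with 2 or more U 1.37, 0.868 and 1.47. Differences in mean length over U-only tails were 0.000207 nt in susi-1(ust1) and 0.000637 nt after cold shock.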

Other observations

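No explanation was tested in this part, and the reads of nrde-3 were looked at only after the data had been seen.

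Most further gene lists in susi-1(R457H) had medians below 0. Its piRNAs were lower in 16 of 27 (median log2 −1.43, percentile 15.3), maternal germline genes in 10 of 15 (−1.35, percentile 33.2), rRNA processing factors in 11 of 21 (−1.13, percentile 58.9), histones in 2 of 4 (−1.34, percentile 19.4), DNA damage genes in 8 of 15 (−1.27, percentile 22.0) and heat shock and cold genes in 6 of 9 (−1.52, percentile 14.4). All of these medians except those of piRNAs and of heat shock and cold genes changed sign when scaled to total microRNA reads. Mitochondrial genes stood slightly above other genes (0.46, percentile 98.3; 1 of 18 higher). With UV in total RNA, ERGO-1 targets were neither in 5 of 6 (0.31, percentile 51.5, with the opposite sign when scaled to total microRNA reads), and pseudogenes (0.02, percentile 8.43), collagens (0.10, percentile 25.9) and mitochondrial genes (0.10, percentile 94.9) lay near 0 and below it under each of the other scalings. No sperm gene (msp) and no yolk gene (vit) had enough reads in any of the 5 small RNA comparisons.

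Reads of nrde-3 itself differed between libraries. Sense reads, which RNA of the tagged transgene would also give, made up 0.0120% of protein-coding sense reads in N2 (31 reads; 0.00816 to 0.0171), 0.0476% in N2 after cold shock (83 reads) and 0.112% in susi-1(R457H) (270 reads; 0.0990 to 0.126), whose labels name no transgene. In the libraries labelled with the transgene they were 0.0902% in eri-1 without UV (421 reads) and 0.168% with UV (1169 reads), and with NRDE-3 4.89% in N2 and 8.32% in eri-1 after cold shock, 0.235% without UV and 0.504% with UV.

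Further genes had far more reads with NRDE-3 than in total RNA of N2 after cold shock. The gene Y43F8B.9 was 191-fold (87.6 to 520.2), Y13C8A.1 98.7-fold (79.0 to 125), W04B5.2 97.8-fold (76.4 to 127) and H37A05.4 95.01-fold (74.8 to 123) higher, and mir-260 14.8-fold (12.7 to 17.4).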
